A study of Mus musculus with 12 samples.

How the data were processed

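RNA was sequenced from cultures of MC38, a mouse colorectal cancer cell line, in 4 groups of 3 libraries: untreated control, nintedanib at 3 µM, X-rays at 8 Gy, and both treatments together. The labels give 24 hours for each treatment. Per the labels, the experiment was repeated independently 3 times, and libraries were made from column-purified total RNA with a SMARTER mRNA kit. Groups and replicate numbers were taken from the sample titles, and each of the 12 value columns carried the title of 1 sample.

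The authors deposited a table of 54532 genes with FPKM values (fragments scaled to gene model length and library depth), gene identifiers, coordinates, gene model lengths and biotypes, per the file headers. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Of the identifiers, 54409 were also in GENCODE M21, and 53499 of those had the same chromosome, start and end there. Coordinates below are those of the deposited table, in GRCm38.

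The depth behind the deposited FPKM values was read from the values themselves. In every library 100% of nonzero values, multiplied by gene model length, were whole multiples of 1 step, within a tolerance of 0.01 of a step. The resulting fragment totals were 16103528 to 18196615 per library. An FPKM of 1 in a gene of 1000 bases therefore stood for 16.4 to 18.7 fragments. Shorter genes rested on fewer fragments at the same FPKM and were measured with less precision. Fragments without molecular identifiers are not independent molecules, and these totals describe counting error only. The authors had also applied a scaling factor per library that the sources used here do not describe. The depth implied by the values was 0.970 to 0.982 of the fragment total in controls and 1.00 to 1.03 in treated libraries.

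Replicates of a group were checked for being 1 library deposited more than once, by a chi-square test of their recovered fragments over genes with at least 20 of them. The statistic per gene was 4.30 to 30.2 in the 12 pairs, so all replicates differed by more than sampling noise and were counted separately.

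Differential expression was tested on log2(FPKM + 1) with limma 3.58.1 (empirical Bayes with an intensity trend, two-sided) in R 4.3.3. All 12 libraries entered 1 fit with a mean per group and 8 residual degrees of freedom. The 13012 genes with an FPKM of at least 1 in at least 3 libraries were tested. P-values were adjusted by Benjamini-Hochberg over those genes in each of 6 comparisons, at a threshold of 0.05, and a second count took genes with an absolute log2 fold change of at least 1. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. The interaction is the effect of nintedanib in irradiated cells minus its effect in unirradiated cells.

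Before the data were examined, 29 gene lists, the tests, the rule for naming genes and most alternative settings were fixed. The lists covered p53 targets, G2/M and mitosis, DNA replication (G1/S), homologous recombination and Fanconi, type I interferon response, MHC class I antigen presentation, chemokine, cytokine and NF-kB targets, immune checkpoints and ligands, senescence and secretory phenotype, TGF-beta and extracellular matrix, drug target receptors and kinases, ligands of those receptors, ERK feedback and immediate early genes, cholesterol synthesis, lysosome and autophagy, the ATF4 integrated stress response, endoplasmic reticulum chaperones, NRF2 and glutathione, ferroptosis, glycolysis and hypoxia, Notch and Wnt targets, YAP targets, apoptosis, mitochondrially encoded genes, cytosolic ribosomal proteins, and markers of epithelial, mesenchymal, leukocyte and endothelial cells. Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Lists with fewer than 5 tested genes were not tested. Members were counted over all genes tested and again adjusted over the list alone.

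Genes were named by this rule: the 10 with the largest positive and the 10 with the largest negative fold change in each comparison with control, and 5 and 5 in the other comparisons. They had to pass the threshold, have a mean FPKM of at least 5 in the higher group and, in comparisons of 2 groups, show no overlap between them. Symbols of predicted genes were passed over. For each list described, up to 4 members with the smallest adjusted p were named, and members of the receptor and marker lists could be named with their level. Some genes that this rule would name are not reported here. Aldoa stood under 2 identifiers in the table and is given for both.

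On simulated data with 100 genes changed at each fold size among the 13012 tested, the fit recovered 46% and 95% of changes of 0.5 and 1 (log2) for nintedanib against control, 44% and 93% for radiation against control, 52% and 90% for the combination against control, 51% and 89% for the combination against radiation, and 45% and 94% for the combination against nintedanib. For the interaction it recovered 16% and 73%. False calls numbered 2 to 12 per comparison, and the changed genes were drawn from genes with a mean of at least 50 fragments. In a set of 30 simulated lists, camera called the 1 shifted list and 0 of the others. Genes were simulated independently of each other, so this says nothing of lists whose members vary together. Each gene's spread was smoothed over genes of like fragment counts, and no deviation shared by many genes of a library was simulated. Recovery and false calls may therefore differ in the real libraries, where deviations ran with gene length (Spearman rho -0.465 to 0.529).

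Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, an FPKM minimum of 5, FPKM rescaled to a common sum, quantile normalization, fits on the groups of a comparison only, no intensity trend, the replicate number as a covariate, and each library left out in turn. Scaling by library totals, voom (limma) on the recovered fragments and a fit on protein-coding genes only were added after seeing the data. Tests on matched lists compared a list's median with those of 10000 random lists matched on gene length and mean log2(FPKM + 1), or on the latter alone for the snoRNA host genes. For the interaction, a test added after seeing the data kept the fitted additive effects and reassigned the deviations from them among the 12 libraries, 100 times with the real order included. Figures and library summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.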

Results

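The transcriptome of MC38 cells was measured in 12 libraries, 3 each from untreated cultures, cultures given nintedanib at 3 µM, cultures given 8 Gy of X-rays, and cultures given both. The labels give 24 hours for each treatment and no time for the controls. Nintedanib is an inhibitor of the VEGF, FGF and PDGF receptor tyrosine kinases. The comparisons ask what the drug and radiation each changed, what the combination changed beyond either one, and whether the effects of both added up.

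Libraries held 16899489, 17836460 and 17698829 fragments in the controls, 17821236, 17246149 and 17830477 with nintedanib, 16103528, 18196615 and 17609684 with radiation, and 17433020, 17356775 and 17460781 with the combination. Protein-coding genes took 97.6 to 98.2% of them, and 12045 to 12373 genes reached an FPKM of 1. Correlations of log2(FPKM + 1) were 0.971 to 0.987 within groups and 0.939 to 0.983 between groups. The first 3 principal components held 44.4, 14.4 and 10.9% of the variance. The third nintedanib library stood apart in its small RNAs: they took 0.137% of its fragments and 0.259 to 0.484% of those of the other libraries, and the 57-base gene Gm23935 was at 609.9 FPKM there and at 12850 to 32370 FPKM elsewhere. Its mitochondrial share, 2.12%, was also the highest, against a lowest of 1.23%.

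**Figure D1:**
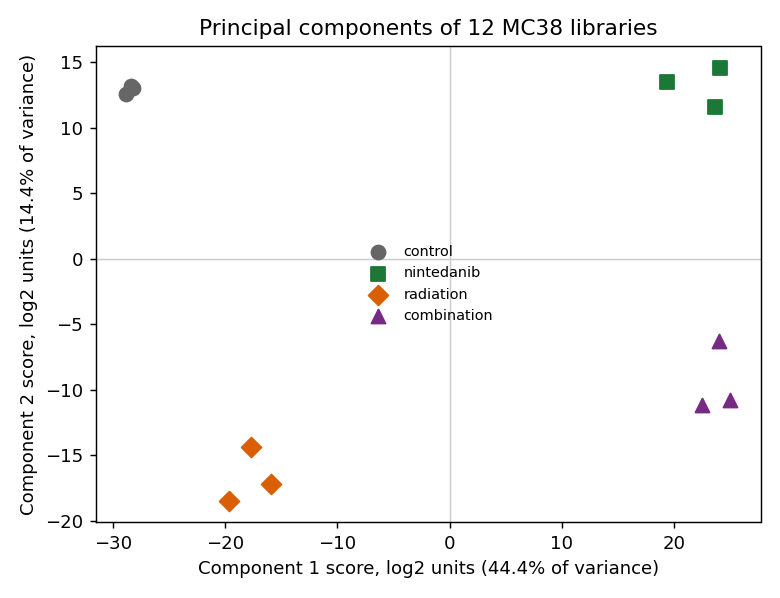
Scores of the 12 libraries on the first 2 principal components of log2(FPKM + 1) over 13012 genes, 1 point per library, coloured by group. The axes hold 44.4% and 14.4% of the variance.

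The cultures had the markers of a mesenchymal-like line. Vim, an intermediate filament protein, was at 579 ± 35.9 FPKM in controls (SD, n = 3). The epithelial adhesion gene Epcam was listed at 0 in all 12 libraries and the pan-leukocyte gene Ptprc reached at most 0.029 FPKM. Among the kinases that nintedanib inhibits, Pdgfrb (13.7 ± 0.586 FPKM), Fgfr1 (24.1 ± 0.924 FPKM) and Pdgfra (2.46 FPKM) were expressed in controls. The VEGF receptor Flt1 was at 0.220 FPKM, and Kdr, Flt4, Fgfr2, Fgfr4, Kit, Ret and Flt3 did not exceed 0.04 FPKM in any library. With nintedanib, Pdgfra rose to 5.40 FPKM (log2 fold change 0.89), Pdgfrb to 21 FPKM (0.58), Met to 4.68 FPKM (0.72) and Fgfr1 to 32.3 FPKM (0.41). Of the 14 receptor and kinase genes tested, 5 rose and 2 fell, over all genes and adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.225).

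Nintedanib against control asks what the drug did in unirradiated cells. With the drug, 24 of 25 cholesterol synthesis genes, 32 of 38 lysosome genes and 23 of 34 glycolysis and hypoxia genes rose, and 36 of 36 ATF4 target genes and 19 of 24 ERK feedback genes fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.0912 to 0.382 with an estimated correlation). The gene with the largest rise was Id2, a regulator that binds and blocks basic helix-loop-helix transcription factors (ENSMUSG00000020644, chromosome 12, 25093799 to 25097140). It rose from 3.77 ± 0.164 to 27.9 ± 6.18 FPKM (SD, n = 3; log2 fold change 2.57, SE 0.199, adjusted p = 2.93e-06). The gene with the largest fall was Car6, a secreted carbonic anhydrase (chromosome 4, 150187015 to 150201332), which went from 25.7 ± 4.91 to 1.47 ± 0.134 FPKM (log2 fold change -3.42, SE 0.182, adjusted p = 3.09e-07). Of 13012 genes tested, 5419 changed, 2559 of them higher and 2860 lower, and 499 changed at least 2-fold (213 higher, 286 lower; 412 to 961 over the other settings).

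Other genes that rose most after nintedanib were Mvd (18.7 ± 2.62 to 117 ± 25.8 FPKM; log2 fold change 2.57, SE 0.228, adjusted p = 7.55e-06), Acat2 (2.40) and Idi1 (2.14), which act in the mevalonate pathway or its acetoacetyl-CoA supply. The surface antigen Psca (2.36), the lipid droplet protein Plin4 (2.19), the matricellular protein Wisp2 (2.16), the mitophagy receptor Bnip3 (2.04), the Id2 relative Id3 (2.03) and the tubulin Tubb2b (2.0) followed. Among genes that fell, the pseudokinase Trib3, an ATF4 target, went from 313 ± 31.3 to 44.1 ± 4.88 FPKM (log2 fold change -2.80, SE 0.205, adjusted p = 2.01e-06; chromosome 2, 152337422 to 152344032). The ETS factor Etv5, transcribed downstream of ERK, went from 15.9 ± 0.334 to 1.74 ± 0.158 FPKM (-2.62, SE 0.093, adjusted p = 6.96e-08; chromosome 16, 22381309 to 22439719). The immediate early factor Egr1 went from 8.79 ± 0.684 to 0.675 ± 0.0928 FPKM (-2.55, SE 0.096, adjusted p = 6.96e-08; chromosome 18, 34859823 to 34864984). The angiopoietin-like factor Angptl6 (-2.84), Sh2d6 (-2.74), the growth arrest gene Gadd45a (-2.70), the AP-1 subunit Fosl1 (-2.59), the mitochondrial thioesterase Acot2 (-2.55) and the skin adhesion protein Cdsn (-2.54) fell as well.

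All 36 ATF4 target genes, which serve amino acid supply and tRNA charging among other roles, fell after nintedanib, over all genes and adjusted over the list alone (median log2 fold change -1.30, camera adjusted p = 5.71e-22). The call was lost with an estimated correlation (adjusted p = 0.277 with an estimated correlation). Members included the tRNA synthetase Eprs (-1.31), the factor Atf3 (-1.78), the arginine transporter Slc7a1 (-1.32) and the folate enzyme Aldh1l2 (-1.28). Of 25 cholesterol synthesis genes, 24 rose and 0 fell, by both adjustments (median 1.49, adjusted p = 1.49e-15, and adjusted p = 0.329 with an estimated correlation), among them Insig1 (1.72), Fdft1 (1.51) and Hmgcs1 (1.67). Lysosome and autophagy genes rose in 32 of 38 cases and fell in 2, and adjusted over the list alone 33 rose and 2 fell (median 0.65, adjusted p = 1.15e-13, and adjusted p = 0.0912 with an estimated correlation). Gpnmb (1.72), the sialidase Neu1 (1.43) and the protease Ctsd (1.23) were among those that rose. ERK feedback and immediate early genes fell in 19 of 24 cases and rose in 2, by both adjustments (median -1.03, adjusted p = 3.67e-09, and adjusted p = 0.287 with an estimated correlation). Etv5 and Egr1 led them, with the ETS factor Etv4 (-2.35) and the growth regulator Myc (-2.17).

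Glycolysis and hypoxia genes rose in 23 of 34 cases and fell in 6 after nintedanib, by both adjustments (median 0.50, adjusted p = 5.19e-05, and adjusted p = 0.382 with an estimated correlation), with Bnip3 (2.04), the triosephosphate isomerase Tpi1 (1.19) and the phosphofructokinase Pfkp (0.63) among the members. The glycolytic aldolase Aldoa stood under 2 identifiers, at a log2 fold change of 1.09 (135 to 289 FPKM) for ENSMUSG00000030695 and -1.58 (17.1 to 5.10 FPKM) for ENSMUSG00000114515. How reads were shared between them is uncertain. Cytosolic ribosomal protein genes fell in 22 of 34 cases and rose in 0, and adjusted over the list alone 28 fell (median -0.41, adjusted p = 8.52e-06, and adjusted p = 0.725 with an estimated correlation): Rpl3 (-0.60), Rpl5 (-0.56), Rpl13a (-0.74) and Rps7 (-0.57). All protein-coding genes with ribosomal protein symbols, a wider set than these 34, took 4.02 to 4.87% of fragments in controls and 3.39 to 3.68% with nintedanib. Type I interferon response genes rose in 11 of 18 cases and fell in 1 (12 and 1 adjusted over the list alone; median 0.37, adjusted p = 0.000706, and adjusted p = 0.382 with an estimated correlation), including Ifit2 (1.26), Ifit3 (1.61), Stat2 (1.0) and Oas1a (0.72). MHC class I antigen presentation genes rose in 9 of 21 cases and fell in 0, by both adjustments (median 0.20, adjusted p = 0.0159, and adjusted p = 0.542 with an estimated correlation), including H2-T22 (0.62), the chaperone Tapbp (0.59), Pdia3 (0.45) and B2m (0.68). DNA replication genes fell in 12 of 30 cases and rose in 0, by both adjustments (median -0.18, adjusted p = 0.0114, and adjusted p = 0.743 with an estimated correlation), including Rfc4 (-0.68), Tk1 (-0.53), Pola1 (-0.41) and Cdt1 (-0.74). Notch and Wnt target genes fell in 8 of 11 cases and rose in 1, by both adjustments (median -0.50, adjusted p = 0.0159, and adjusted p = 0.542 with an estimated correlation). Myc, the cyclin Ccnd1 (-1.11) and the ligand Jag1 (-0.94) fell and the factor Tcf7 (0.94) rose. Myc and Ccnd1 are members of the ERK list as well. The Notch and Wnt list holds 25 genes, and Axin2, Lgr5 and Hey1 were among those too low to be tested. The interferon list holds 36 genes. Rsad2 (at most 0.103 FPKM in any library), Mx1 (0.385 FPKM) and Ifit1 (0.529 FPKM) were among its members too low to be tested.

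For nintedanib against control, 51.1% of genes had groups that did not overlap, against 10% by chance. The share of changed genes that were higher was 47.2%, and 60.3% after each library's FPKM were rescaled to a common sum. Without the third nintedanib library 5038 genes changed. The DNA replication call was lost in 2 other settings (adjusted p up to 0.0791), as was the Notch and Wnt call (up to 0.125).

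Radiation against control asks what 8 Gy changed at 24 hours. After it, 27 of 30 G2/M and mitosis genes, 12 of 21 MHC class I genes and 9 of 29 recombination and Fanconi genes rose. So did 6 of the 18 interferon response genes high enough to be tested. In turn 12 of 36 ATF4 target genes and 12 of 24 ERK genes fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.161 to 0.596 with an estimated correlation). The chemokine Ccl9 rose from 4.19 ± 0.308 to 22 ± 0.975 FPKM (SD, n = 3; log2 fold change 2.15, SE 0.178, adjusted p = 7.88e-05; chromosome 11, 83572919 to 83578636). The linker histone gene H1f0 went from 581 ± 73.9 to 222 ± 13.5 FPKM (-1.38, SE 0.121, adjusted p = 9.21e-05; chromosome 15, 79028450 to 79030504). Of 13012 genes, 2334 changed, 1046 higher and 1288 lower, and 75 changed at least 2-fold (54 higher, 21 lower). The latter count was 39 with protein-coding genes only, 226 with FPKM rescaled to a common sum, 247 with a pseudocount of 0.1 and 264 with voom.

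The interferon-induced gene Ifi27l2a rose from 5.53 ± 1.15 to 21.4 ± 2.45 FPKM after radiation (1.79, SE 0.166, adjusted p = 0.000108; chromosome 12, 103442167 to 103443680). The mitotic cyclin Ccnb2 rose from 54.3 ± 1.73 to 124 ± 3.91 FPKM (1.17, SE 0.091, adjusted p = 5.86e-05; chromosome 9, 70407692 to 70421547). The cell cycle phosphatase Cdkn3 (1.27), the spindle genes Aspm (1.20), Kif20a (1.18), Knstrn (1.18) and Nusap1 (1.14), the ubiquitin ligase G2e3 (1.14) and the acyl-CoA synthetase Acsbg1 (1.24) rose too. Myc fell from 176 ± 6.03 to 74.2 ± 5.37 FPKM (-1.24, SE 0.085, adjusted p = 3.57e-05; chromosome 15, 61985391 to 61990374). Other genes that fell were the histone genes Hist1h4k (-1.35), Hist1h1c (-1.08) and H2afj (-0.99, adjusted p = 0.0206), the folate carrier Slc19a1 (-1.14), Egr1 (-1.14), the natriuretic peptide Nppb (-1.10), the microRNA cluster host Mir17hg (-1.0) and the small nucleolar RNA Snord83b (-1.33, adjusted p = 0.0202). The calls of Snord83b and H2afj were lost in 5 of 22 and 3 of 23 other settings.

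Of 30 G2/M and mitosis genes, 27 rose and 0 fell after radiation, and adjusted over the list alone 29 rose (median 0.69, adjusted p = 2.24e-28, and adjusted p = 0.161 with an estimated correlation); Kif2c rose by 0.81. MHC class I genes rose in 12 of 21 cases and fell in 1 (14 and 1 adjusted over the list alone; median 0.38, adjusted p = 1.66e-06, and adjusted p = 0.271 with an estimated correlation), including H2-T22 (0.63), H2-Q4 (0.54), Tapbp (0.47) and the immunoproteasome subunit Psmb9 (0.64). Homologous recombination and Fanconi genes rose in 9 of 29 cases and fell in 0 (14 and 3 adjusted over the list alone; median 0.21, adjusted p = 0.000114, and adjusted p = 0.482 with an estimated correlation), with Fancg (0.66), Fancd2 (0.51) and Blm (0.52). Interferon response genes rose in 6 of 18 cases and fell in 0, by both adjustments (median 0.24, adjusted p = 0.000302, and adjusted p = 0.482 with an estimated correlation), including the RNA sensor Ddx58 (0.64), Oas1a (0.63), Trim30a (0.62) and Igtp (0.43). Endoplasmic reticulum chaperone genes rose in 7 of 23 cases and fell in 1, by both adjustments (median 0.14, adjusted p = 0.00136, and adjusted p = 0.482 with an estimated correlation). Hsp90b1 (0.65), Selenos (0.53) and Edem1 (0.38) rose and the sensor Atf6 (-0.39) fell. DNA replication genes rose in 5 of 30 cases and fell in 3 (9 and 4 adjusted over the list alone; median 0.19, adjusted p = 0.0344, and adjusted p = 0.696 with an estimated correlation). Cdc45 (0.35), Mcm3 (0.50) and Mcm10 (0.39) rose, and Ung (-0.91) fell.

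ATF4 target genes fell after radiation in 12 of 36 cases and rose in 0 (14 and 0 adjusted over the list alone; median -0.26, adjusted p = 3.72e-05, and adjusted p = 0.596 with an estimated correlation), including Atf3 (-0.77), the phosphatase subunit Ppp1r15a (-0.86), Stc2 (-0.71) and Slc38a2 (-0.52). ERK feedback and immediate early genes fell in 12 of 24 cases and rose in 1 (14 and 2 adjusted over the list alone; median -0.38, adjusted p = 3.94e-05, and adjusted p = 0.482 with an estimated correlation), with the ERK phosphatases Dusp5 (-0.58) and Dusp6 (-0.58) beside Myc and Egr1. Lysosome genes fell in 10 of 38 cases and rose in 0, by both adjustments (median -0.14, adjusted p = 0.00708, and adjusted p = 0.482 with an estimated correlation), including Ctsa (-0.48), Flcn (-0.52) and Ctsd (-0.32). The 34 ribosomal protein genes had a median of -0.19 (adjusted p = 0.00865, and adjusted p = 0.696 with an estimated correlation), with 0 members passing by either adjustment; Rpl13a had -0.42 (adjusted p = 0.0638). The wider set of all ribosomal protein genes took 3.74 to 4.39% of fragments with radiation. The 26 p53 target genes, the transcriptional response to DNA damage, were not called as a list (median 0.00, adjusted p = 0.819). Among them 1 rose and 3 fell, by both adjustments: Psrc1 (0.42) rose, and Bbc3 (-0.99), Aen (-0.54) and Bax (-0.53) fell. The cell cycle inhibitor Cdkn1a was at 30.5 ± 2.67 FPKM in controls and 32.9 ± 1.34 FPKM after radiation, and the p53 antagonist Mdm2 at 9.26 and 8.56 FPKM. Cholesterol synthesis genes had 0 members past the threshold (adjusted p = 0.24).

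For radiation against control, 41.8% of genes had groups that did not overlap, against 10% by chance. The share of changed genes that were higher was 44.8%, 70.6% after rescaling to a common sum and 59.9% after scaling by library totals. The count fell to 1333 without the second control library, 1250 without the third control library, 1523 without the first radiation library and 1145 without the second. Calls of named members were lost in 7 of 23 settings for Cdc45, Mcm3 and Mcm10, 6 for Bax, 4 for Aen and Ctsd and 1 for Atf6. For Igtp and Psrc1 they were lost in 6 and 2 of 22. In other settings the ribosomal call was lost in 4 (adjusted p up to 0.29), the lysosome call in 2 (up to 0.157) and the DNA replication call in 2 (up to 0.0731).

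The combination against control asks what both treatments changed together. With both, 24 of 25 cholesterol synthesis genes, 30 of 38 lysosome genes and 22 of 34 glycolysis and hypoxia genes rose. So did 20 of 30 mitosis genes, 15 of 21 MHC class I genes and 14 of the 18 interferon response genes high enough to be tested. In turn 34 of 36 ATF4 target genes and 20 of 24 ERK genes fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.109 to 0.392 with an estimated correlation). The largest rise was that of Ifi27l2a, from 5.53 ± 1.15 to 43.2 ± 7.52 FPKM (SD, n = 3; log2 fold change 2.76, SE 0.166, adjusted p = 5.04e-07). The immune checkpoint receptor Havcr2 rose from 0.914 to 7.18 FPKM (2.10, adjusted p = 2.28e-07; chromosome 11, 46454935 to 46481255). In all, 6148 genes changed, 2898 higher and 3250 lower, and 679 changed at least 2-fold (341 higher, 338 lower), with 56.8% of genes in groups that did not overlap, against 10% by chance. The share of changed genes that were higher was 47.1%, 55.7% with FPKM rescaled to a common sum and 55.6% with library totals. The 2-fold count was 1077, 1202 and 1236 with FPKM rescaled, a pseudocount of 0.1 and voom.

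Other genes that rose most with the combination were Id2 (2.64), Tubb2b (2.58), Psca (2.40), Acat2 (2.29), Mvd (2.27), the serpin Serpinb8 (2.17), the autophagy regulator Trp53inp2 (2.10) and the adhesion molecule Mcam (2.09). Those that fell most were Car6 (-3.25), Cdsn (-3.08), Angptl6 (-2.86), Trib3 (-2.69), Etv5 (-2.65), Acot2 (-2.60), Myc (-2.53), Sh2d6 (-2.48), Egr1 (-2.48) and Fosl1 (-2.44). ATF4 target genes fell in 34 of 36 cases (36 adjusted over the list alone) and rose in 0 (median -1.23, adjusted p = 2.76e-18, and adjusted p = 0.237 with an estimated correlation). Cholesterol synthesis genes rose in 24 of 25 cases and fell in 0, by both adjustments (median 1.32, adjusted p = 7.26e-13, and adjusted p = 0.307 with an estimated correlation). Lysosome genes rose in 30 of 38 cases and fell in 2 (32 and 2 adjusted over the list alone; median 0.58, adjusted p = 7.37e-13, and adjusted p = 0.109 with an estimated correlation). ERK feedback and immediate early genes fell in 20 of 24 cases and rose in 2, by both adjustments (median -0.89, adjusted p = 1.13e-08, and adjusted p = 0.237 with an estimated correlation).

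G2/M and mitosis genes rose with the combination in 20 of 30 cases and fell in 0 (22 and 0 adjusted over the list alone; median 0.47, adjusted p = 3.72e-07, and adjusted p = 0.392 with an estimated correlation), including Ccnb2 (1.16), Ccnb1 (0.99), Nusap1 (0.95) and Kif20a (0.93). Interferon response genes rose in 14 of 18 cases and fell in 0, by both adjustments (median 0.53, adjusted p = 9.68e-06, and adjusted p = 0.237 with an estimated correlation), with Stat2 (1.04), Oas1a (1.01), Bst2 (0.96) and Ifit2 (0.90). MHC class I genes rose in 15 of 21 cases and fell in 0, by both adjustments (median 0.52, adjusted p = 4.83e-05, and adjusted p = 0.237 with an estimated correlation), with Psmb8 (1.06), H2-T22 (1.03), Tapbp (0.86) and H2-K1 (0.84). Glycolysis and hypoxia genes rose in 22 of 34 cases and fell in 6, by both adjustments (median 0.61, adjusted p = 0.000108, and adjusted p = 0.378 with an estimated correlation). Ribosomal protein genes fell in 10 of 34 cases and rose in 0 (8 and 0 adjusted over the list alone, median -0.24, camera adjusted p = 0.0169, and adjusted p = 0.79 with an estimated correlation). The wider set of all ribosomal protein genes took 3.40 to 4.27% of fragments. Notch and Wnt target genes fell in 8 of 11 cases and rose in 1, by both adjustments (median -0.57, adjusted p = 0.0169, and adjusted p = 0.469 with an estimated correlation). NRF2 and glutathione genes rose in 13 of 27 cases and fell in 5 (13 and 7 adjusted over the list alone; median 0.22, adjusted p = 0.0427, and adjusted p = 0.615 with an estimated correlation). Mgst1 (1.77), Gstm1 (0.86) and the catalase Cat (0.55) rose, and the cystine transporter Slc7a11 (-1.79) fell. Endoplasmic reticulum chaperone genes rose in 13 of 23 cases and fell in 4 (13 and 5 adjusted over the list alone; median 0.33, adjusted p = 0.0435, and adjusted p = 0.615 with an estimated correlation). Selenos (0.84) and Hsp90b1 (0.78) rose, and the sensors Atf6 (-1.11) and Ern1 (-0.67) fell. In other settings the ribosomal call was lost in 3 (adjusted p up to 0.173), the Notch and Wnt call in 2 (up to 0.0905), the NRF2 call in 6 (up to 0.101) and the chaperone call in 5 (up to 0.101).

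**Figure D2:**
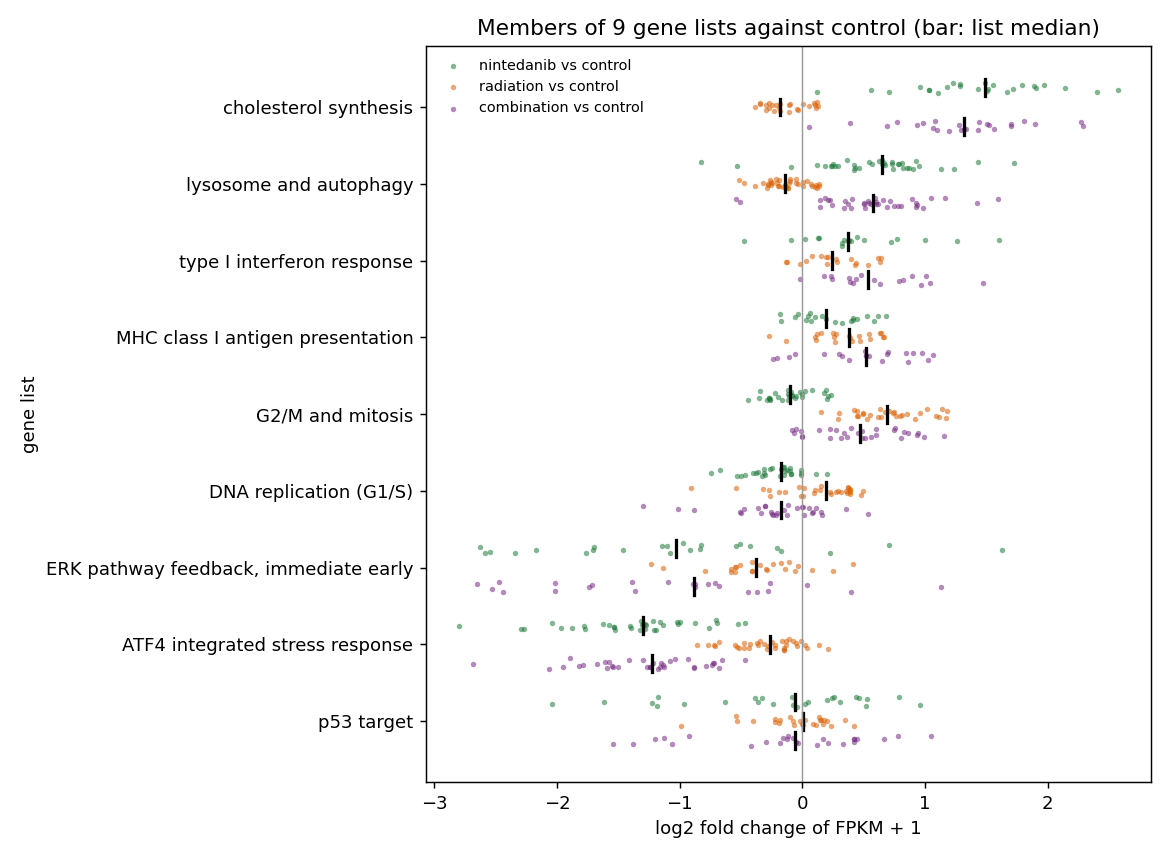
Log2 fold change against control of the members of 9 gene lists (1 point per gene, bar at the list median) for nintedanib, radiation and the combination (n = 3 per group). ATF4 target genes had medians of -1.30, -0.26 and -1.23, and G2/M and mitosis genes -0.10, 0.69 and 0.47.

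The combination against radiation asks what the drug did in irradiated cells. There, 24 of 25 cholesterol synthesis genes, 33 of 38 lysosome genes and 25 of 34 glycolysis and hypoxia genes rose. Falls were seen in 33 of 36 ATF4 target genes, 17 of 24 ERK genes, 14 of 30 DNA replication genes and 11 of 30 G2/M genes. Except for the lysosome list, the calls of these lists were lost with an estimated correlation (adjusted p = 0.226 to 0.567 with an estimated correlation). Psca (2.58), Mvd (2.57), Id2 (2.45), Wisp2 (2.26) and Acat2 (2.23) rose most, and Car6 (-3.37), Etv5 (-2.90), Angptl6 (-2.82), Cdsn (-2.67) and Sh2d6 (-2.47) fell most. In all, 4478 genes changed, 2232 higher and 2246 lower, and 347 changed at least 2-fold (204 higher, 143 lower), with 47.4% of genes in groups that did not overlap, against 10% by chance. The 2-fold count was 561 with a pseudocount of 0.1 and 579 with voom.

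In irradiated cells lysosome genes rose with the drug in 33 of 38 cases and fell in 2 (35 and 2 adjusted over the list alone; median 0.67, adjusted p = 2.21e-19). This was the 1 list call, over the 6 comparisons, that held with an estimated correlation (adjusted p = 0.0301 with an estimated correlation). Gpnmb (1.8), Neu1 (1.68), Ctsd (1.48) and the proton pump subunit Atp6v0d1 (1.33) were among its members. ATF4 target genes fell in 33 of 36 cases and rose in 0 (34 and 0 adjusted over the list alone; median -0.99, adjusted p = 4.77e-20, and adjusted p = 0.226 with an estimated correlation). Cholesterol synthesis genes rose in 24 of 25 cases and fell in 0, by both adjustments (median 1.47, adjusted p = 1.43e-17, and adjusted p = 0.265 with an estimated correlation). Glycolysis and hypoxia genes rose in 25 of 34 cases and fell in 3 (27 and 3 adjusted over the list alone; median 0.57, adjusted p = 4.06e-09, and adjusted p = 0.226 with an estimated correlation). ERK feedback and immediate early genes fell in 17 of 24 cases and rose in 2, by both adjustments (median -0.68, adjusted p = 7.53e-07, and adjusted p = 0.318 with an estimated correlation). G2/M and mitosis genes fell in 11 of 30 cases and rose in 0 (13 and 0 adjusted over the list alone; median -0.22, adjusted p = 7.5e-05, and adjusted p = 0.562 with an estimated correlation), including Top2a (-0.63), Kif23 (-0.50), Ndc80 (-0.46) and Bub1b (-0.31). DNA replication genes fell in 14 of 30 cases and rose in 0 (15 and 0 adjusted over the list alone; median -0.29, adjusted p = 0.00011, and adjusted p = 0.567 with an estimated correlation), with Pola1 at -0.63 and Uhrf1 at -0.78. Homologous recombination and Fanconi genes fell in 10 of 29 cases and rose in 0 (12 and 0 adjusted over the list alone; median -0.18, adjusted p = 0.0052, and adjusted p = 0.562 with an estimated correlation), including Fancd2 (-0.45), Rbbp8 (-0.46) and Mre11a (-0.42). Interferon response genes rose in 5 of 18 cases and fell in 0, by both adjustments (median 0.18, adjusted p = 0.0052, and adjusted p = 0.534 with an estimated correlation), including Ifit3 (1.5), Bst2 (1.08), Ifit2 (0.82) and Stat2 (0.77). Notch and Wnt target genes fell in 7 of 11 cases and rose in 1 (8 and 1 adjusted over the list alone; median -0.40, adjusted p = 0.00678, and adjusted p = 0.534 with an estimated correlation). The last of these calls was lost in 1 other setting (adjusted p = 0.0528). NRF2 and glutathione genes rose in 12 of 27 cases and fell in 3 (15 and 4 adjusted over the list alone; median 0.27, adjusted p = 0.0102, and adjusted p = 0.562 with an estimated correlation).

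The drug's fold changes with and without radiation, taken from separate libraries, correlated across 13012 genes (Pearson r = 0.751, Spearman rho = 0.713, slope 0.655). Of the 5419 genes changed by nintedanib alone, 95.1% had the same sign in irradiated cells, and 3416 genes were called in both in the same direction, against 933 expected of independent calls. Genes are not independent replicates, and noise in the fold changes lowers the slope. Both comparisons use the same estimate of each gene's spread. Their calls are therefore not independent even without a shared effect, and 933 may be too low a reference.

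The combination against nintedanib asks what radiation did in drug-treated cells. There, 21 of 30 G2/M and mitosis genes and 5 of 21 MHC class I genes rose, and 4 of 21 YAP target genes fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.163 to 0.3 with an estimated correlation). The chemokine Ccl9 rose from 3.13 ± 0.585 to 12.3 ± 3.91 FPKM (SD, n = 3; log2 fold change 1.65, SE 0.178, adjusted p = 0.000937), the secreted protein Spp1 (osteopontin) from 38.6 ± 6.53 to 96.8 ± 3.18 FPKM (1.32, SE 0.12, adjusted p = 0.000492) and the mitotic kinase Aurka from 45.4 to 100 FPKM (1.13, SE 0.1, adjusted p = 0.000464). Ifi27l2a (1.40) and the keratin Krt13 (1.06) rose too. The small nucleolar RNA Snord65 (-2.06, SE 0.315, limma adjusted p = 0.00491), H1f0 (-1.0), the growth arrest gene Gas1 (-0.88), Ctgf (-0.83) and the clock output gene Dbp (-0.81) fell. Snord65 is 72 bases long and went from 5.15 to 0.521 FPKM. At 100 bases an FPKM of 1 stood for 1.6 to 1.9 fragments, so the Snord65 call rests on few fragments. In all, 722 genes changed, 413 higher and 309 lower, and 29 changed at least 2-fold (21 higher, 8 lower), with 22.2% of genes in groups that did not overlap, against 10% by chance. The 2-fold count was 14 in a fit of these 2 groups alone and also with protein-coding genes only. It was 15 with an FPKM minimum of 5, 58 with FPKM rescaled to a common sum, 83 with a pseudocount of 0.1 and 93 with voom. Without the first nintedanib library it was 50.

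In drug-treated cells G2/M and mitosis genes rose with radiation in 21 of 30 cases and fell in 0 (29 and 0 adjusted over the list alone; median 0.51, adjusted p = 3.1e-28, and adjusted p = 0.163 with an estimated correlation), with Kif20a (1.02), Ccnb2 (0.96) and Kif2c (0.72) beside Aurka. MHC class I genes rose in 5 of 21 cases and fell in 0 (11 and 0 adjusted over the list alone; median 0.30, adjusted p = 1.3e-05, and adjusted p = 0.3 with an estimated correlation), including Psmb8 (0.67), H2-Q4 (0.55), H2-D1 (0.47) and H2-K1 (0.43). YAP target genes fell in 4 of 21 cases and rose in 1 (8 and 1 adjusted over the list alone; median -0.18, adjusted p = 0.000546, and adjusted p = 0.3 with an estimated correlation). Ctgf, Amotl2 (-0.53) and Ankrd1 (-0.45) fell and Nuak2 (0.49) rose. The 34 ribosomal protein genes had a median of 0.16 (adjusted p = 0.000691, and adjusted p = 0.822 with an estimated correlation) and 0 members passing by either adjustment. Homologous recombination and Fanconi genes rose in 2 of 29 cases and fell in 1 (9 and 2 adjusted over the list alone; median 0.13, adjusted p = 0.0162, and adjusted p = 0.751 with an estimated correlation). NRF2 genes rose in 2 of 27 cases, Osgin1 (0.61) and Nqo1 (0.37), and fell in 0, by both adjustments (median 0.14, adjusted p = 0.0162, and adjusted p = 0.723 with an estimated correlation). Interferon response genes rose in 2 of 18 cases, Cxcl10 (0.71) and Oas1a (0.28), and fell in 0 (2 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.0243, and adjusted p = 0.723 with an estimated correlation). Chemokine, cytokine and NF-kB target genes rose in 2 of 14 cases, the NF-kB subunits Nfkb2 (0.42) and Relb (0.38), and fell in 1, Csf1 (-0.31) (3 and 1 adjusted over the list alone; median 0.22, adjusted p = 0.0398, and adjusted p = 0.642 with an estimated correlation). Of the 26 p53 target genes, Cdkn1a (0.51, adjusted p = 0.0362), Plk2 (0.26) and Sesn2 (0.50) rose and 0 fell, by both adjustments, and the list was not called (adjusted p = 0.258).

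Library choice moved the count for the combination against nintedanib: it was 269 without the second combination library, 357 without the second nintedanib library, 432 without the third combination library and 453 without the third nintedanib library. It was 43 in a fit of these 2 groups alone. Calls of named genes were lost in other settings as well: Plk2 in 17, Sesn2 in 16, Cdkn1a in 12, Relb in 11, Nqo1 and Csf1 in 9, Dbp and H2-D1 in 7, H2-K1 in 6, Psmb8 in 4, Ctgf and Osgin1 in 3, Nfkb2 and Ankrd1 in 2 and Amotl2 and H2-Q4 in 1 of 23. Those of other genes were lost for Oas1a in 10, Nuak2 in 2 and Cxcl10 in 1 of 22. Of the list calls, the chemokine call was lost in 5 (adjusted p up to 0.344), the recombination call in 4 (up to 0.308), the NRF2 call in 3 (up to 0.19) and the interferon call in 3 (up to 0.349). Radiation's fold changes with and without the drug, again from separate libraries, correlated less closely across genes (Pearson r = 0.397, Spearman rho = 0.386, slope 0.343). In each gene they differ by the interaction, the same amount by which the drug's fold changes with and without radiation differ. The lower correlation therefore does not show that the drug altered radiation's effect more than radiation altered the drug's. Of the 2334 genes changed by radiation alone, 87.9% had the same sign with the drug present, and 491 were called in both in the same direction, against 64 expected of independent calls. These calls too share each gene's estimate of spread, so 64 may be too low a reference. Leaving out 1 library at a time gave 0.687 to 0.773 for the drug's correlation and 0.280 to 0.451 for that of radiation.

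The interaction asks whether the effects of drug and radiation added up on the log scale. Egr1 was the 1 gene that differed: it was at 8.79 ± 0.684 FPKM in controls, 0.675 ± 0.0928 with nintedanib, 3.47 ± 0.507 with radiation and 0.759 ± 0.025 with the combination (SD, n = 3), so that the drug's effect was smaller by 1.21 (log2) in irradiated cells (SE 0.136, limma adjusted p = 0.0281). At an unadjusted p under 0.05 there were 1685 genes. The Egr1 call was lost in 13 of 22 other settings (adjusted p 0.00402 to 0.212). The count was 0 without any 1 of the 3 control libraries, nintedanib library 2 or 3, radiation library 1 or 2, or combination library 2 or 3, and 5 without nintedanib library 1 or combination library 1.

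Among gene lists, 10 were called for the interaction, each with an adjusted p = 0.57 with an estimated correlation. The medians of ATF4 target genes (0.29, adjusted p = 6.45e-09), ribosomal protein genes (0.33, adjusted p = 6.45e-09), ERK feedback and immediate early genes (0.27, adjusted p = 0.000115), ferroptosis genes (0.25, adjusted p = 0.00266), lysosome genes (0.14, adjusted p = 0.00266), glycolysis genes (0.14, adjusted p = 0.0165) and NRF2 genes (0.16, adjusted p = 0.0447) lay above 0. Those of G2/M and mitosis genes (-0.14, adjusted p = 0.000115), recombination and Fanconi genes (-0.12, adjusted p = 0.0447) and endoplasmic reticulum chaperone genes (-0.10, adjusted p = 0.0447) lay below 0. Over all genes tested, Egr1 was the 1 member that passed. Adjusted over the list alone, 6 of 36 ATF4 target genes passed with an interaction above 0 and 0 below 0, with Atf3 at 0.88 and Ppp1r15a at 1.06. Of 24 ERK genes, 7 passed above 0 and 1 below 0, with Myc at 0.88. By that adjustment 3 of 34 glycolysis genes and 1 of 23 ferroptosis genes, Ptgs2 (0.66), passed above 0. In the other called lists 0 members passed. An interaction above 0 is not a rise in level: Myc had its lowest mean with the combination (29.8 FPKM). In other settings the glycolysis call was lost in 3 (adjusted p up to 0.162), the lysosome call in 3 (up to 0.335), the recombination call in 10 (up to 0.336), the NRF2 call in 12 (up to 0.335) and the chaperone call in 11 of 22 (up to 0.223).

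**Figure D3:**
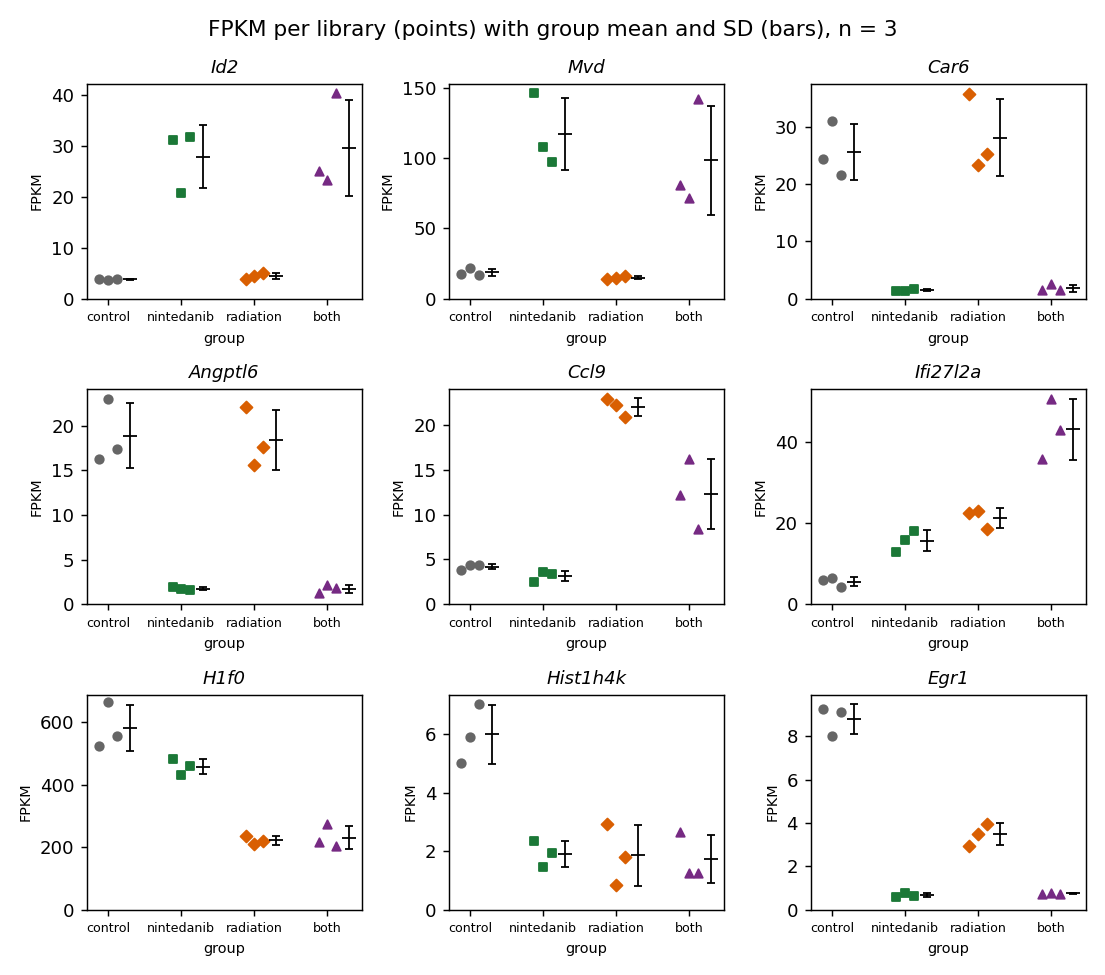
FPKM of 9 named genes in each of the 12 libraries, 1 point per library, with the group mean and SD as bars (n = 3). Egr1 stood at a mean of 8.79 FPKM in controls and 0.675, 3.47 and 0.759 FPKM with nintedanib, radiation and the combination.

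Lists without a call in any comparison still had members that changed. Of all genes tested, 41.6% changed after nintedanib, 17.9% after radiation and 47.2% with the combination, so changed members alone do not set a list apart. Of 31 apoptosis genes, 8 rose and 4 fell after nintedanib by both adjustments, 2 rose and 4 fell after radiation (3 and 5 adjusted over the list alone), and 9 rose and 7 fell with the combination by both. The p53-induced killer gene Bbc3 fell in each (-1.17, -0.99 and -1.38). Of 15 senescence and secretory genes, 4, 2 and 5 rose and 8, 5 and 7 fell, and adjusted over the list alone 4, 2 and 5 rose and 8, 6 and 7 fell. The plasminogen activators Plau (1.67) and Plat (1.59) and the protease Mmp14 (1.28) rose after nintedanib, and Igfbp4 (-1.44) fell. Of 29 TGF-beta and matrix genes, 10, 3 and 13 rose and 5, 4 and 7 fell (10, 4 and 14, and 5, 5 and 7, adjusted over the list alone). Tgfb2 rose after nintedanib (0.78) and fell after radiation (-0.62), and the matrix cross-linking enzyme Loxl2 rose after radiation (1.07). Of 12 immune checkpoint and ligand genes, 4, 3 and 5 rose and 5, 1 and 5 fell (5, 4 and 5, and 5, 1 and 6, adjusted over the list alone). The costimulatory ligand Icosl (-1.05) and the anti-phagocytic signal Cd47 (-0.69) fell after nintedanib, and Lgals9 (0.73) and Cd276 (0.42) rose. The checkpoint ligand Cd274 fell in the combination against radiation (-0.77), from 2.40 to 0.985 FPKM. Of 9 ligands of the drug's target receptors, 3, 1 and 3 rose and 2, 4 and 4 fell, by both adjustments, including Csf1 (-0.80) and Vegfa (-0.75) after nintedanib and Nrp2 (-0.71) after radiation.

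Of 18 mesenchymal and fibroblast markers, 6 rose and 1 fell after nintedanib, 1 rose and 0 fell after radiation, and 6 rose and 1 fell with the combination, by both adjustments; the collagen gene Col1a2 rose by 0.94 and the factor Snai2 fell by 0.70 after nintedanib. Of 5 epithelial markers, 1, 1 and 2 rose and 1, 0 and 1 fell (2, 1 and 2, and 1, 0 and 1, adjusted over the list alone), and the adhesion gene Cdh1 rose from 4.49 to 8.26 FPKM with the combination (0.76). Of 15 mitochondrially encoded genes, 4, 0 and 2 rose and 0 fell (2, 0 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.0643, 0.199 and 0.114); the third nintedanib library had the highest mitochondrial share. With 3 tested genes each, leukocyte and endothelial markers were not tested as lists. The lysosomal protein Cd68, a macrophage marker, rose from 4.0 ± 0.541 to 14 ± 0.409 FPKM with nintedanib (SD, n = 3; log2 fold change 1.59, adjusted p = 7.42e-07) and to 17.7 ± 1.67 FPKM with the combination (1.90), while Ptprc stayed at or under 0.029 FPKM. The macrophage lysozyme Lyz2 was at 0.208 FPKM in controls and 0.829 FPKM with nintedanib (0.59, adjusted p = 0.0317, lost in 6 of 22 other settings). The 3 endothelial markers tested had 0 calls against control. In some lists with members on both sides of 0 and no call, the median and the test differed in sign: ferroptosis and apoptosis genes after nintedanib (medians -0.12 and -0.003, tests higher), NRF2 genes after radiation (median -0.06, test higher), and, with the combination, receptor genes (median -0.08, test higher) and their ligands (median 0.11, test lower).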

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

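The tests of scaling, of cycling overall and of histone genes on the G2/M pattern, of single libraries and scaling on the ribosomal pattern, and of low values, scaling and the drug's own level on the stress and ERK pattern, and the reassignment of deviations from additive effects, were chosen only after the result was seen. The effect of nintedanib differed between irradiated and unirradiated cells by a test of the interaction for 1 gene and 10 gene lists. The call of each list was lost with an estimated correlation (adjusted p = 0.57 with an estimated correlation).

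Egr1 had an interaction of 1.21 (log2). Its call was lost in 13 of 22 other settings. Chance was not excluded for the count of 1 gene: with the additive effects kept and the deviations from them reassigned among the 12 libraries, 10 of 100 reassignments, the real one included, called as many. The highest of the others called 610, which points to a structure of the samples, and its source was not tested. Deviations from the group mean ran with gene length in single libraries (Spearman rho across genes -0.465 in the second control to 0.529 in the first combination library). Nor was chance excluded for the 10 lists, with 18 of 100 reassignments calling as many and the highest of the others 12. Splits of the samples that assign whole libraries to other groups put the drug's effect into the residual and decide neither count: 1 of 100 called as many genes (highest other 0), and 30 of 100 as many lists (highest other 15). Lysosome genes had a median interaction of 0.14, glycolysis genes 0.14, NRF2 genes 0.16, ferroptosis genes 0.25, recombination and Fanconi genes -0.12 and chaperone genes -0.10. G2/M genes had a median interaction of -0.14.

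ATF4 target genes had a median interaction of 0.29 and ERK genes one of 0.27, and of their 60 members together 53 lay above 0 (median 0.28), so the combination moved them less than the sum of both treatments. Low values near the pseudocount were argued against, since the 48 members with a mean FPKM of at least 5 in every group had a median of 0.285, and so was a bias of gene length and expression, since the median lay at percentile 100 of 10000 lists matched on gene length and mean log2(FPKM + 1), which gave 0.016 to 0.143. The size of the shift depended on scaling. The median was 0.155 with FPKM rescaled to a common sum, 0.231 with library totals and 0.186 with quantile normalization. Medians of all genes were -0.119, -0.033 and -0.017 there. The members' median lay above that of all genes under each, which argues against a scaling common to all genes as the whole cause. At the preset correlation the ATF4 and ERK calls held in all 22 other settings (camera adjusted p up to 8.89e-06 and 0.00205). A candidate explanation is that nintedanib alone already brought these genes to the level of the combination, at which radiation could lower them no further. The mean over members was 0.037 higher with the combination than with nintedanib (95% interval -0.148 to 0.223), which does not settle it, and chance was not excluded for the list calls (18 of 100 reassignments).

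Ribosomal protein genes had a median interaction of 0.33, with 34 of 34 members above 0. Lists matched on gene length and mean log2(FPKM + 1) shifted by 0.216 (0.134 to 0.296), and the observed median lay at percentile 99.74 of them. Ribosomal protein genes beyond the 34 were not kept out of these lists, so their shift may contain part of the pattern. The matched lists therefore do not decide how much a bias of length or expression adds. A single library was argued against, since leaving out 1 at a time gave medians of 0.234 (without the second control) to 0.417 (without the first combination library). Scaling stays open, with medians of 0.134 after quantile normalization, 0.193 with FPKM rescaled to a common sum and 0.278 with library totals. Whether the shift reflects the treatments stays untested, and chance was not excluded for the list calls (18 of 100 reassignments).

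G2/M and mitosis genes rose after radiation with a median of 0.69, and this kept its size under 3 other scalings (lowest median 0.748) and lay at percentile 100 of 10000 matched lists, which gave -0.159 to 0.014. The mean of the G2/M list rose by 0.6 more than that of the replication list (SD within groups 0.09). This argues against more cells in the cycle as the whole cause only if both lists respond alike to it, which was not tested. A hypothesis is that irradiated cells may have accumulated in G2 or M phase, which leaves open why DNA replication genes also lay higher (median 0.19, 21 of 30 above 0, camera adjusted p = 0.0344, and adjusted p = 0.696 with an estimated correlation). A smaller share of cells in S phase would lower replication-dependent histone genes, which are transcribed in S phase. The libraries came from an mRNA kit, and how fully it captured histone transcripts was not tested. Histone values therefore do not settle the share of cells in S phase. The histone median was -0.345, 21 of 22 lay below 0 and 5 fell, against -0.154 to 0.231 in matched lists. Under other scalings the median was -0.31, -0.446 and -0.43. In drug-treated cells, where radiation also raised G2/M genes, the histone median was -0.045, with 13 of 22 below 0, 0 lower and 1 higher, low only against matched lists (percentile 0.71 of lists that gave 0.001 to 0.344), and after nintedanib it was -0.268 without a rise of G2/M genes, so the hypothesis stays open.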

How the results depend on the processing

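Scaling by library totals, voom on the recovered fragments and the fit on protein-coding genes only were chosen only after the results were seen. Of the named genes, lists, correlations and counts, 0 reversed direction under any setting, but the balance of higher and lower calls turned. Over rescaling to a common sum, library totals and quantile normalization, higher genes were 60.3, 55.8 and 51.4% of those changed by nintedanib (47.2% as reported), 70.6, 59.9 and 53.5% for radiation (44.8%) and 55.7, 55.6 and 50.7% for the combination (47.1%). The median fold change of all genes turned positive in these comparisons under the first 2 of those scalings. Gene counts for nintedanib, the combination against control and the combination against radiation stayed within 1.5 times under every setting run; where causes are not given, the cause was not tested.

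The count of genes for the interaction, 1 as reported, was 0 with a pseudocount of 0.1, 12 with no filter on low values, 3 with an FPKM minimum of 5, 3 with FPKM rescaled to a common sum, 0 with library totals, 4 with protein-coding genes only and 20 with voom. It was 0 to 5 with 1 library left out. For the combination against nintedanib 722 genes became 43 in a fit of these groups alone, and 269 to 652 with 1 library left out. Its count of lists was 5 with an FPKM minimum of 5, against 8. Fewer samples alone do not explain the 43. Such fits gave 4675 genes for nintedanib (5419 as reported) and 6010 for the combination (6148). They gave 4215 for the combination against radiation (4478) and 2784 for radiation (2334). Chi-square per gene between replicates was 13.3 to 30.2 with nintedanib and 10.45 to 16.6 with both. It was 4.30 to 12.2 in controls and 7.69 to 10.7 with radiation. The main fit uses 1 spread per gene for all groups, and whether it suits these 2 was not tested. For radiation against control, leaving out 1 library gave 1145 to 2606 genes. With an estimated correlation 1 list was called for the combination against radiation, and 0 lists in each of the other 5 comparisons.

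The correlation of the drug's fold changes with and without radiation, 0.751, was 0.601 with a pseudocount of 0.1, 0.681 with no filter, 0.838 with an FPKM minimum of 5, 0.679 with FPKM rescaled to a common sum, 0.851 with protein-coding genes only, 0.673 with voom and 0.687 to 0.773 with 1 library left out. That of radiation's fold changes, 0.397, was 0.302 with a pseudocount of 0.1, 0.339 with no filter, 0.538 with protein-coding genes only and 0.280 to 0.451 with 1 library left out. Counts of genes changed at least 2-fold moved by over 1.5 times in 23 cases under other settings and in 12 with a library left out. With a pseudocount of 0.1, FPKM rescaled and voom they were 903, 809 and 961 for nintedanib (499 as reported), 247, 226 and 264 for radiation (75), 1202, 1077 and 1236 for the combination (679) and 83, 58 and 93 for the combination against nintedanib (29). The common sum lay above the library sums of 268411 to 315358 FPKM, so the added 1 weighed less after rescaling. These counts therefore do not tell a scaling effect from a pseudocount effect. For the combination against radiation (347) they were 561 with the pseudocount and 579 with voom. With an FPKM minimum of 5 and with protein-coding genes only, radiation had 41 and 39 and the combination against nintedanib 15 and 14, and the latter had 14 in a fit of its groups alone and 50 without the first nintedanib library. For the interaction (1) the count was 0 with the pseudocount, the replicate block and library totals, 5 with voom and 0 to 2 with 1 library left out. Calls of lists were lost in 98 and 45 cases, and calls of named genes in 171 and 333.

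The replicate numbers did not pair the libraries. In 18 same-number pairs the correlations of deviations from the group means were -0.298 to 0.202, with 3 over 0.1, and 4 of 12 libraries correlated best with their own number. With the replicate number as a block, 5091, 1795 and 5785 genes changed against control (nintedanib, radiation, combination), 4074 and 444 in the combination against radiation and against nintedanib, and 0 in the interaction; 27 calls of single genes or lists were lost.

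Small changes were recovered in part: in data simulated at these depths with 3 libraries per group, 44 to 52% of genes changed by 0.5 (log2) were recovered in the comparisons of groups, and 16% in the interaction.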

Other observations

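The tests on snoRNA host genes and on fatty acid synthesis genes were chosen only after the result was seen, as were the gene lists of this part.

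Host genes of small nucleolar RNAs, noncoding transcripts that carry those RNAs in their introns, fell after nintedanib in 12 of 14 cases (median log2 fold change -1.09). Snhg12 (-2.20), Zfas1 (-2.12), Snhg5 (-2.06) and Gas5 (-1.33) fell, and Snhg18 (1.17) rose. Their median lay at percentile 0 of 10000 lists matched on mean log2(FPKM + 1). After radiation 3 of the 14 fell and 0 rose (median -0.35). The third nintedanib library had the lowest share of small RNAs. Genes of fatty acid synthesis rose after nintedanib in 10 of 11 cases, with a median of 0.992, beside the rise of cholesterol synthesis genes: Elovl6 (1.89), Acss2 (1.75), Fasn (1.44) and Scd2 (1.14) rose, and Elovl5 stood at 0.12 and did not pass. The 3 tested Id genes, Id1 (1.37), Id2 (2.57) and Id3 (2.03), which block basic helix-loop-helix factors, rose together.

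Cytosolic aminoacyl-tRNA synthetase genes outside the ATF4 list fell after nintedanib in 11 of 13 cases (median -0.64), with Lars at -1.46, Tars at -1.35 and Iars at -1.25. Mitochondrial synthetase genes had a median of -0.101, with 4 of 17 lower and 1 higher. A hypothesis in line with these values is that the fall followed the ATF4 program, whose known targets include cytosolic synthetases, rather than tRNA charging in general. Both sets lay close after radiation (medians -0.211 for cytosolic and -0.172 for mitochondrial genes). With the combination the medians were -0.533 and -0.267, and 8 of 17 mitochondrial synthetase genes fell. ATF4 protein or its binding was not analysed here.

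Other splits of the 6 libraries of a comparison, each fitted with all 12 libraries, do not decide the gene counts. Each mixes libraries of both groups, which puts their difference into the residual and lowers the gene calls. Besides, 10 splits are too few for a share under 0.05. The real split gave 5419 genes for nintedanib, and the highest other split 1. For radiation these were 2334 and 3, for the combination 6148 and 0, for the combination against radiation 4478 and 2, and for the combination against nintedanib 722 and 0, so 1 of 10 splits, the real one, gave as many genes each time. For gene lists, splits with as many calls as the real one numbered 4 of 10 for nintedanib (10 lists, highest other 11), 1 for radiation (10, highest other 8), 3 for the combination (12, highest other 12), 2 for the combination against radiation (11, highest other 14) and 5 for the combination against nintedanib (8, highest other 10).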
